A study of Mus musculus with 6 samples.

How the data were processed

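Expression was measured with an Affymetrix mouse expression array in 6 samples of hindlimb muscle myoblasts, 3 grown on collagen I and 3 on fibronectin for 72 hours. Per the labels' protocols the cells were kept in Ham's F-10 medium with serum and basic fibroblast growth factor, harvested with trypsin and pelleted, and total RNA was extracted with a bead-based kit and labelled with biotin. The values are the log2 probe set signals deposited by the authors, and per the submitters' processing notes the tools used were Affymetrix Expression Console and RMA, which corrects background, normalises probes across arrays by quantiles and summarises probe sets on a log2 scale. Software versions, RMA settings and scan dates are not given in the sources used here, so batches could not be tested. Any normalisation across arrays assumes that the distribution of signals is alike in all samples, so a change shared by most genes would be removed. RMA also compresses changes of dim probe sets, whose signals approach a floor. The lowest value was -0.172 and the highest 12.7, and sample medians lay between 2.30 and 2.39.

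Groups were taken from the sample titles. The values were used as deposited, without further normalisation. Gene names came from the annotation of the array platform, updated through a gene reference of assembly GRCm38.p6, in which 18032 of 18194 gene identifiers were found. Of 45101 probe sets 34945 had 1 gene, 932 had several and were not named, and 9211 had no entry, including 64 control probe sets. Chromosome positions are not given, since no source used here ties the array's annotation to a genome build. Each gene was represented by its probe set with the highest mean over all samples. Genes were tested if that mean reached 2.33, the median over all probe sets, which left 10941 of 18194 genes and put 7253 below the filter. Array signals give no count of molecules, so precision was judged from the 3 samples per group alone.

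The comparison of coatings was fitted with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes with default settings, two-sided, fibronectin minus collagen, no covariates), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The moderated variances combined 4 residual with 3.81 prior degrees of freedom. With 3 samples against 3 an exact permutation test of a single gene cannot give a p below 0.1, so no such test was run. Gene lists were tested with camera from limma, with a preset correlation of 0.01, adjusted over 33 lists with at least 5 tested members. The other 4 of 37 lists were described by level. The lists held 1317 entries, of which 1231 had a measured gene. For each list, members past the gene test were counted over all genes and with p-values adjusted over the list alone. Camera with a correlation estimated per list and fry were run beside it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

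The tests, the gene lists, the alternatives other than those for the similarity of samples and the rule for naming genes were fixed before the data were examined. The rule named the 10 largest rises and the 10 largest falls among genes past the threshold whose samples did not overlap between coatings, leaving out predicted genes, up to 4 members of each list past its threshold, 20 fixed genes, and up to 3 members of any other list described, each by smallest unadjusted p. Of the 20 fixed genes 1 is not reported here. Alternatives were no brightness filter, a filter at the 75th percentile, quantile normalisation again, centring on sample medians, the mean of all probe sets of a gene, an intensity trend with robust variance, array weights, the replicate number as a block, leaving out each sample in turn, stricter thresholds and all probe sets with or without a gene.

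The procedure was tested on simulated data for the same comparison, with 10941 genes of which 200 were changed. It recovered 86% of genes changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold or 3-fold, with 8 false calls among 201, and it called the 1 shifted list and 0 others. In 50 simulations without any change 0 called a list and 2 called a gene. The simulated genes were drawn independently, so they do not test camera on correlated genes.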

Results

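Myoblasts, the dividing precursor cells of skeletal muscle, were prepared from hindlimb muscle of male C57BL/6JRj mice and grown for 72 hours on dishes coated with fibronectin or with collagen I. Fibronectin is a matrix glycoprotein bound through integrins such as Itga5 and Itgav, and collagen I is a fibrillar collagen bound through other integrins, including Itga1 and Itga2. Total RNA from 3 samples per coating, 6 samples in all, was hybridised to an Affymetrix mouse expression array, and the comparison asked how the substrate changed gene expression in the cells. The deposited log2 signals covered 45101 probe sets. Sample medians lay between 2.35 and 2.39 on collagen and between 2.30 and 2.34 on fibronectin. The number of samples limited the precision, and the median SE of a log2 change was 0.06. The labels do not say that the samples came from separate cultures or animals, so the p-values measured only the spread between these samples, which may be technical.

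The 6 samples separated by coating. Over the tested genes the first principal component held 78.8% of the variance, with collagen samples at -16.8, -15.4 and -14.1 and fibronectin samples at 17.3, 14.2 and 14.8. Pearson correlations across all probe sets other than controls, which are not independent replicates, lay between 0.997 and 0.998 within a coating and between 0.994 and 0.995 across coatings. Leaving out 1 sample at a time gave a first component of 79% to 82.1%, and testing without the brightness filter gave 60.7%.

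On fibronectin, cells had lower signals for genes of the contractile apparatus and of muscle differentiation, and higher signals for genes of DNA replication and mitosis, than on collagen I. Myog, a transcription factor that drives myoblast differentiation, fell 1.78-fold, and Mki67, a marker of cycling cells, rose 1.36-fold. Myod1 and Myf5, transcription factors of the muscle lineage, had log2 changes of -0.06 and 0.08 and did not pass the test. Genes of lysosomes and of the antioxidant response were lower on fibronectin, and genes of amino acid synthesis and ribosome biogenesis were higher. All of these list calls were made by the camera test with a preset correlation between genes. Each was lost with an estimated correlation, a setting that also changes the degrees of freedom of the test, at adjusted p between 0.125 and 0.419. Of 10941 genes tested with limma, 4384 passed an adjusted p of 0.05, 2173 of them higher and 2211 lower on fibronectin. Most of the changes were small. The median size of the log2 change among genes past the threshold was 0.30, and 572 genes changed by at least 1.5-fold, of which 170 rose and 402 fell. Changes of at least 2-fold were found in 146 genes, 36 of them higher and 110 lower. The balance of directions depended on the scaling, since centring each sample on its median gave 2973 higher and 1646 lower genes, or 64.4% higher in place of 49.6%.

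The largest rise was that of Gzmd (Entrez gene 14941), a serine protease of cytotoxic granules, from 2.37 ± 0.38 on collagen to 4.78 ± 0.10 on fibronectin (SD, n = 3), a 5.32-fold change with a log2 SE of 0.17 and an adjusted p of 5.9e-05. The collagen signal of Gzmd lay close to the brightness filter of 2.33, and its probe set is of a type that can bind transcripts of related genes. Col8a1 (Entrez gene 12837), a short-chain collagen, rose from 3.78 ± 0.28 to 5.90 ± 0.10, or 4.36-fold (adjusted p = 3.17e-05). Akap12, a scaffold for protein kinase A, rose 3.61-fold, and the growth factor receptor Egfr rose 3.19-fold, with a log2 SE of 0.075 each. The other 6 of the 10 largest rises were those of Cxadr, a cell adhesion protein that serves as a virus receptor (2.92-fold), Sostdc1, a secreted antagonist of BMP and Wnt signals (2.85-fold), Cth, an enzyme of cysteine synthesis (2.72-fold), the actin-binding protein Nebl (2.72-fold), Slc35f1 (2.69-fold) and the matrix glycoprotein Thbs1 (2.61-fold). Adjusted p over these 10 genes lay between 8.81e-06 and 0.000452.

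Klra17 (Entrez gene 170733), a lectin-like receptor, had the largest fall, from 4.26 ± 0.28 on collagen to 1.63 ± 0.33 on fibronectin (log2 change -2.63, SE 0.18, adjusted p = 5.79e-05). The collagenase Mmp13 had a log2 change of -2.08, from 3.72 ± 0.24 to 1.64 ± 0.12. The fibronectin signals of both genes lay below the brightness filter, so the sizes of their falls rest on values near the array's floor. Whrn (Entrez gene 73750), a scaffold protein of sensory hair cells, went from 5.75 ± 0.08 to 3.27 ± 0.19, a fall of 5.62-fold (adjusted p = 8.81e-06). Syndig1 fell 4.7-fold and Fam102a fell 4.34-fold. Fabp4 and Fabp7, carriers of fatty acids, fell 4.28-fold and 3.73-fold. Mb, the oxygen-binding myoglobin of muscle, fell 3.49-fold, with a wider SD among the fibronectin samples (0.45) than among the collagen samples (0.10). Atp13a4, a cation-transporting ATPase, fell 3.26-fold, and the growth factor Tgfb1 fell 3.23-fold, from 6.74 ± 0.07 to 5.04 ± 0.25.

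**Figure D1:**
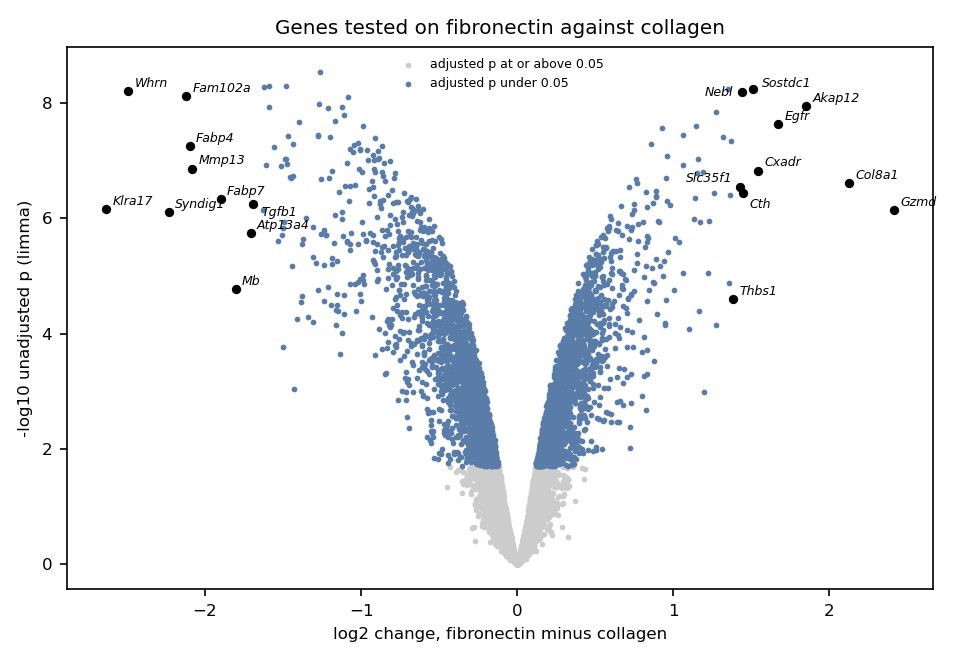
Log2 change (fibronectin minus collagen, x axis) against -log10 of the unadjusted limma p (y axis) for the 10941 genes tested, with the 10 largest rises and the 10 largest falls labelled. Blue points are the 4384 genes with an adjusted p under 0.05, and black points, which passed too, run from Klra17 at -2.63 to Gzmd at 2.41.

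Of 20 genes chosen before the data were examined for their place in adhesion, the muscle lineage or the cell cycle, 19 are reported here, 14 were bright enough to test and 4 passed. Myog fell from 4.81 ± 0.19 to 3.98 ± 0.20 (log2 change -0.83, SE 0.12, adjusted p = 0.00132), and Mki67 rose from 8.59 ± 0.01 to 9.04 ± 0.10 (log2 change 0.45, SE 0.06, adjusted p = 0.000807). Fn1, which encodes fibronectin itself, fell by 0.25 on the log2 scale (adjusted p = 0.0109), as did the Wnt receptor Fzd7 (adjusted p = 0.00998). Neither Fn1 nor Fzd7 passed when all probe sets of a gene were averaged, with log2 changes of -0.23 and -0.01. Pax7, a transcription factor of muscle stem cells, had a log2 change of -0.13 (SE 0.05, adjusted p = 0.086), and Myf5 and Myod1 had adjusted p of 0.364 and 0.289. The integrin subunits Itga5, Itga7, Itgav and Itgb1 had log2 changes of 0.19, -0.03, 0.11 and 0.01 and did not pass, and neither did Sdc4, a proteoglycan that binds fibronectin (log2 change 0.18), Ccnd1 (-0.09) or the cell cycle inhibitor Cdkn1a (0.01). Itga5 passed without fibronectin replicate 3, at a log2 change of 0.27, and Sdc4 passed without collagen replicate 1, at 0.26, whereas the mean over all its probe sets gave Itga5 -0.13. With samples centred Itga5, Itgav and Sdc4 passed, at 0.25, 0.17 and 0.23. With an intensity trend and robust variance Itgav, Sdc4, Pax7 and Ccnd1 passed at the changes given above. Pax7 and Sdc4 passed with the 75th percentile filter too, Sdc4 with array weights (0.21) and Pax7 with averaged probe sets (-0.25). Col1a1, Itga1, Itga2, Itgb3 and Ckm lay below the filter on both coatings, with means of at most 2.08.

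**Figure D2:**
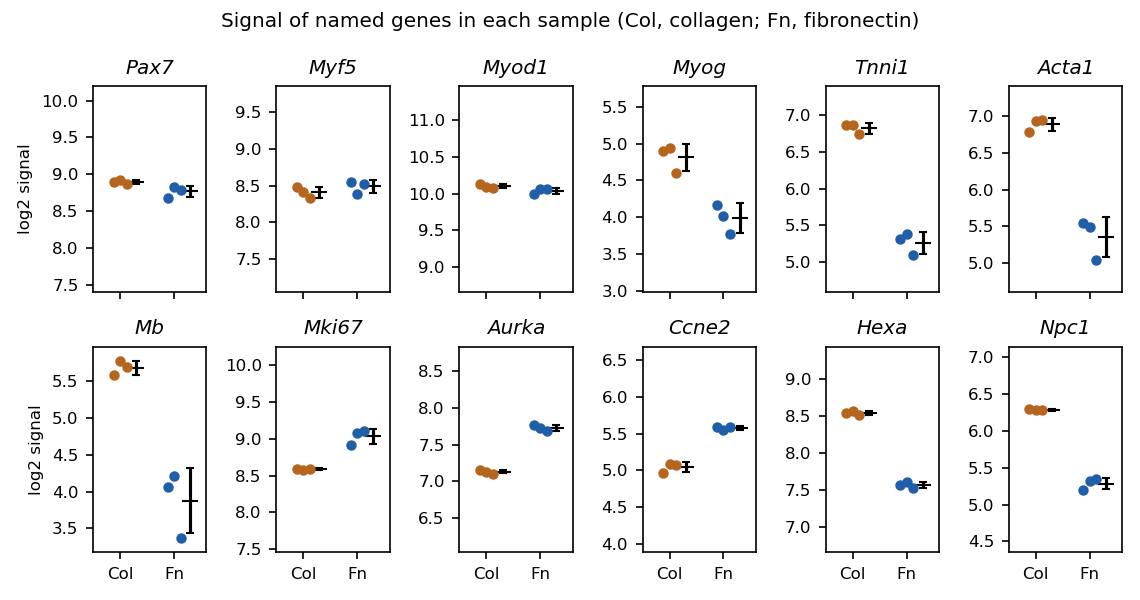
Log2 signal (y axes, each spanning the same range) of 12 genes in the 3 samples on collagen (Col) and the 3 on fibronectin (Fn); coloured points are samples and black bars are the mean ± SD. Mean signals of Pax7, Myf5 and Myod1 differed by at most 0.13 between coatings. Myog, Tnni1, Acta1, Mb, Hexa and Npc1 were lower and Mki67, Aurka and Ccne2 higher in each fibronectin sample than in any collagen sample. Pax7 and Myod1 were also lower in each fibronectin sample than in any collagen sample, but did not pass the test.

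Muscle differentiation and sarcomere genes fell together on fibronectin. Of 46 tested members of this list 42 fell and 0 rose (adjusted over the list alone, 44 fell and 0 rose), and the median log2 change was -0.71. Tnni1, a troponin of slow muscle, fell 2.95-fold from 6.82 ± 0.07 to 5.26 ± 0.15. Musk, a receptor kinase of the nerve-muscle synapse, fell 2.32-fold, and the transcription factor Mef2c and the troponin Tnnt2 fell 1.89-fold and 1.75-fold. Chrnb1, Ckb, Eno3 and Jsrp1, named after their values were seen, were the members that did not pass. By limma's camera test with a preset correlation between genes the list had an adjusted p of 8.31e-17, and adjusted p = 0.199 with an estimated correlation. The wider list of stem cell and myoblast identity genes did not pass as a list (camera adjusted p = 0.201), with 5 of 22 tested members higher and 10 lower (the same counts adjusted over the list alone). Among them Cxcr4, a chemokine receptor, fell 2.27-fold, Spry1, an inhibitor of receptor kinase signalling, fell 2.03-fold, and the syndecan Sdc3 fell 1.42-fold.

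Cell cycle genes rose on fibronectin, by less than the differentiation genes fell. Of 75 tested genes of mitosis 70 rose and 1, Pttg1, fell (adjusted over the list alone, 72 rose and 1 fell), with a median log2 change of 0.41. The mitotic kinase Aurka rose from 7.13 ± 0.02 to 7.72 ± 0.04, or 1.51-fold, the kinase Melk rose 1.5-fold, and Sgo1 and Cenpa, proteins of the centromere, rose 1.48-fold and 1.42-fold. Of 55 tested genes of DNA replication 43 rose and 1, Cdt1, fell (adjusted over the list alone, 48 rose and 1 fell), with a median of 0.28. Pttg1 and Cdt1 were named after their values were seen. Ccne2, a cyclin of the start of S phase, rose 1.45-fold, and Exo1, E2f7 and Pola1 rose 1.42-fold, 1.42-fold and 1.37-fold. Pola1 did not pass with its probe sets averaged (log2 change 0.08). The mitosis list had a camera adjusted p of 1.01e-23 (adjusted p = 0.125 with an estimated correlation), and the replication list 4.4e-13 (adjusted p = 0.132 with an estimated correlation). The list of cell cycle inhibitors and DNA damage response genes did not pass (adjusted p = 0.246), with 9 of 28 members higher and 5 lower (likewise adjusted over the list alone), among them Gadd45a at -0.75, Plk2 at 0.67 and Ei24 at 0.49.

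Genes of amino acid synthesis and uptake controlled by the transcription factor Atf4 were higher on fibronectin, with 22 of 38 tested members up and 2 down, counts that were the same adjusted over the list alone, and a median log2 change of 0.26. Psat1 and Phgdh, enzymes of serine synthesis, rose 1.78-fold and 1.58-fold, Cth rose as given above, and the transcription factor Cebpg rose 1.39-fold. Camera gave this list an adjusted p of 4.36e-05 (adjusted p = 0.419 with an estimated correlation). Of 49 tested genes of ribosome biogenesis and Myc targets 30 rose and 1, Nhp2, named after its value was seen, fell (adjusted over the list alone, 35 rose and 1 fell), and the median was 0.19. Srm, which makes spermidine, rose 1.3-fold, the transcription factor Myc rose from 7.04 ± 0.02 to 7.36 ± 0.05, and Rrp9 and Ddx18, which act in ribosomal RNA processing, rose by 0.35 and 0.32 on the log2 scale. Its camera adjusted p was 3.23e-07 (adjusted p = 0.385 with an estimated correlation). Glycolysis and hypoxia response genes had 17 of 30 members higher and 4 lower (adjusted over the list alone, 18 and 5), with a median of 0.19. Pdk1, a kinase that restrains pyruvate oxidation, rose 1.7-fold, the phosphofructokinases Pfkl and Pfkp rose 1.57-fold and 1.37-fold, and Bnip3 rose 1.34-fold. The camera adjusted p was 0.00233 (adjusted p = 0.244 with an estimated correlation).

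Lysosome and autophagy genes were lower on fibronectin, with 24 of 33 tested members down and 2 up, the same counts as adjusted over the list alone, and a median log2 change of -0.31. Hexa, a lysosomal hexosaminidase, fell from 8.55 ± 0.03 to 7.56 ± 0.04, or 1.99-fold. Npc1, which exports cholesterol from lysosomes, fell 2-fold, the protease Ctsa fell 1.85-fold, and Sqstm1, an autophagy receptor, fell 1.73-fold. The members that rose, named after their values were seen, were Bnip3 and Fbxo32. Camera gave an adjusted p of 1.59e-08 (adjusted p = 0.2 with an estimated correlation). Genes of the antioxidant response controlled by the transcription factor Nrf2 fell in 20 of 34 cases and rose in 1, Gsr, named after its value was seen, with the same counts adjusted over the list alone, and the median was -0.24. Mt1, a metal-binding metallothionein, fell 2.28-fold, the glutathione transferase Gsta3 fell 2.4-fold and the heme oxygenase Hmox1 fell 1.93-fold. Its camera adjusted p was 1.16e-06 (adjusted p = 0.125 with an estimated correlation).

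The TGF-beta and BMP list holds ligands, receptors and other components of the pathways as well as targets, so it does not measure target output alone. Of its 25 tested members 12 were lower and 1, Ltbp1, named after its value was seen, was higher (the same counts adjusted over the list alone). The median log2 change was -0.12. Besides Tgfb1, the falls included Id4, an inhibitor of transcription factors, at 1.98-fold, the inhibitory Smad6 at 1.64-fold and Ltbp3, which binds latent TGF-beta, at 1.5-fold. The camera adjusted p was 0.00237 (adjusted p = 0.367 with an estimated correlation), and the median was -0.07 with samples centred, -0.08 without the brightness filter and -0.19 without collagen replicate 1. Genes of endoplasmic reticulum chaperones and the unfolded protein response had 12 of 31 members lower and 1, Herpud1, named after its value was seen, higher (the same counts adjusted over the list alone), with a median of -0.10. The members with the smallest p were the stress sensors Eif2ak3 and Atf6, which fell 1.33-fold each, Dnajb9, a cochaperone, which fell 1.43-fold, and Selenok, a membrane selenoprotein, which fell 1.28-fold. Its camera adjusted p was 0.0302 (adjusted p = 0.367 with an estimated correlation) and, over the settings run with camera, lay between 0.0148 and 0.367, and its median was -0.04 with samples centred. The call was lost without collagen replicate 2 (adjusted p = 0.0719), without fibronectin replicate 1 (0.0618) and without fibronectin replicate 2 (0.0537).

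**Figure D3:**
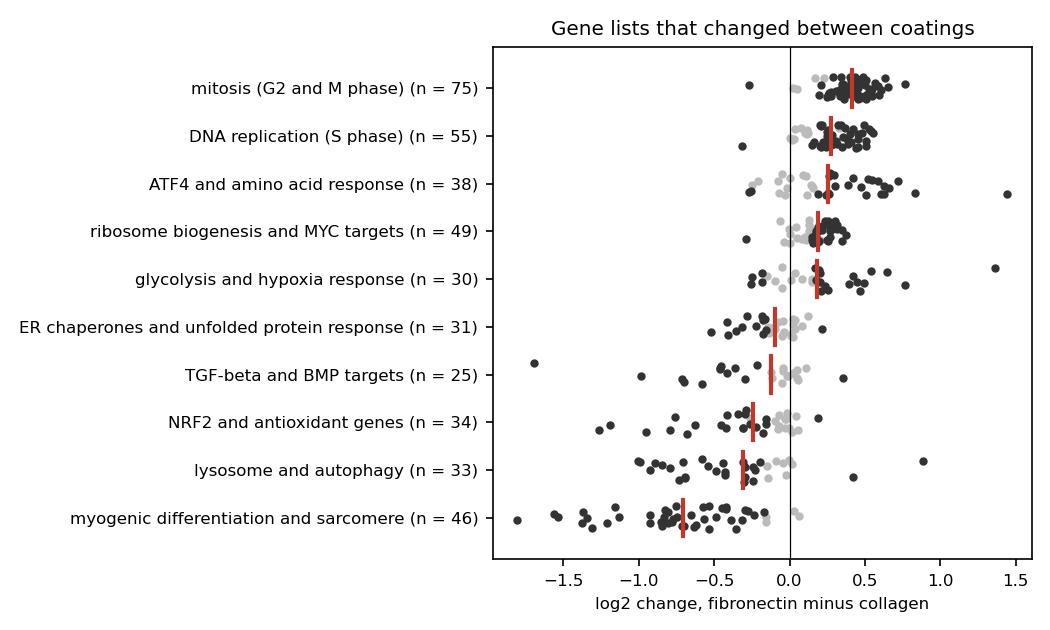
Log2 change (fibronectin minus collagen, x axis) of each tested member of the 10 gene lists past the camera threshold with a preset correlation, with the number of tested members after each name; dark points are genes with an adjusted p under 0.05, grey points are the rest and red bars are medians, and the vertical scatter has no meaning. The medians ran from -0.71 for differentiation and sarcomere genes to 0.41 for mitosis genes.

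Of the 33 lists tested with camera, 10 passed with the preset correlation of 0.01, 5 higher and 5 lower. With a correlation estimated for each list 0 passed the adjusted threshold, and 6 had an unadjusted p under 0.05. The directional test fry, which asks whether a list's own genes move one way on balance and does not set them against other genes, called 26 lists, among them all 10 in the same direction.

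Genes of cell adhesion moved both ways, and camera, which sets a list against other genes, did not call their lists. Within the lists fry found the integrin, actin and Yap and Taz genes higher on balance, with adjusted p of 0.0092, 0.00611 and 0.00311, and did not call the focal adhesion genes (0.0964). Of 12 tested integrin subunits 4 rose and 1 fell (camera adjusted p = 0.197), with Itga4 at a log2 change of 0.53, Itga6, a laminin receptor subunit, at 0.44 and Itga3 at 0.29, which did not pass with its probe sets averaged (0.16). Focal adhesion components had 7 of 37 members higher and 7 lower (adjusted p = 0.743). The cytoskeletal adaptor Pdlim1 rose 2.5-fold, the membrane protein Cav1 rose 1.83-fold and Zyx, which sits at the ends of actin bundles, rose 1.5-fold. Counts adjusted over the list alone were the same for both lists. Actin cytoskeleton genes and targets of the transcription factor Srf had 13 of 38 members higher and 10 lower (adjusted over the list alone, 14 and 12; adjusted p = 0.645). They included the skeletal muscle actin Acta1, which fell 2.89-fold, and Cdc42ep3, which rose 1.63-fold. Targets of Yap and Taz rose in 12 of 25 cases and fell in 5, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.201). Ccn1, a matrix-associated signalling protein, rose 2.19-fold, Ajuba rose 1.68-fold and the ectonucleotidase Nt5e fell 2.73-fold.

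Collagens had 6 of 14 tested members higher and 3 lower (adjusted over the list alone, 6 and 4) and a camera adjusted p of 0.0771. Col5a1 rose 2.54-fold, from 5.89 ± 0.05 to 7.24 ± 0.06, and the basement membrane collagen Col4a2 rose 1.58-fold. Matrix glycoproteins rose in 7 of 20 cases and fell in 5 (adjusted over the list alone, 7 and 6; adjusted p = 0.463). Vcan, a large proteoglycan, rose 1.97-fold, Tnc rose 1.81-fold and Fbln1 rose 1.59-fold. Matrix remodelling enzymes and their inhibitors had 9 of 26 members higher and 10 lower, the same adjusted over the list alone (adjusted p = 0.246), including the protease Ctsb, which fell 1.62-fold, and Timp2, an inhibitor of matrix metalloproteinases, which fell 1.78-fold.

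Signalling lists were mixed. Immediate early and Erk feedback genes had 9 of 40 members higher and 13 lower (adjusted over the list alone, 9 and 15; camera adjusted p = 0.201), and the phosphatases Dusp2 and Dusp1 fell 2.25-fold and 1.45-fold. Components of the p38 kinase pathway rose in 3 and fell in 4 of 25 cases (adjusted p = 0.85), with Mapk13 down 1.83-fold and Dusp10 up 1.46-fold. Growth factors and receptors of muscle cells had 4 of 22 members higher and 9 lower (adjusted p = 0.138), with Igfbp4, which binds insulin-like growth factors, down 2.74-fold and Igf2r down 1.83-fold. In the Notch list 3 of 19 rose and 3 fell (adjusted p = 0.85). The ligands Dll1 and Jag1 fell 1.98-fold and 1.82-fold, and Dtx4 rose 1.75-fold. Counts for these 3 lists were the same adjusted over the list alone. Wnt pathway genes rose in 7 and fell in 3 of 20 cases (adjusted over the list alone, 8 and 3; adjusted p = 0.201), with Ccn4, Apcdd1 and the receptor Fzd4 up 1.64-fold, 1.55-fold and 1.44-fold. Chemokines, cytokines and NF-kB targets had 6 of 18 higher and 4 lower (adjusted over the list alone, 6 and 5; adjusted p = 0.852), among them Ccl7 at -0.66, Csf1 at 0.45 and Cxcl12 at 0.37, which did not pass with its probe sets averaged (0.10). Interferon response genes had 5 of 23 higher and 6 lower, the same adjusted over the list alone (adjusted p = 0.767), with Irgm1 at -0.46, Ifit2 at 0.42 and Tap1 at 0.30. For the actin, p38 and chemokine lists the median change had the opposite sign to the mean, the test or both, and lay within 0.02 of 0 in each.

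Among metabolic and housekeeping lists, fatty acid and lipid storage genes had 7 of 25 members higher and 10 lower, the same adjusted over the list alone (camera adjusted p = 0.214). The transcription factor Pparg fell 2.7-fold and the lipid droplet protein Plin2 fell 1.72-fold. Cholesterol synthesis genes rose in 2 and fell in 7 of 21 cases, the same adjusted over the list alone (adjusted p = 0.445), with Tm7sf2 at -0.53, Mvd at -0.45 and Lss at -0.31. Heat shock proteins had 7 of 20 higher and 5 lower (adjusted over the list alone, 8 and 6; adjusted p = 0.368), with Fkbp4 at 0.35, Stip1 at 0.25 and the small heat shock protein Cryab at -0.54. Oxidative phosphorylation genes had 2 of 46 members higher and 0 lower (adjusted over the list alone, 0 and 0; adjusted p = 0.525), Cyc1 at 0.17 and Atp5g1 at 0.12, the latter not past the threshold without any 1 of the 6 samples (0.11 to 0.13), without the brightness filter, with quantile normalisation, with probe sets averaged (0.07) or with the replicate number as a block. Of 34 cytosolic ribosomal proteins 2 were higher and 0 lower (adjusted over the list alone, 1 and 0; adjusted p = 0.168), Rpl14 at 0.32 and Rpl12 at 0.27, which did not pass without the brightness filter (0.27) or without fibronectin replicate 2 (0.25). This list passed, as higher on fibronectin, with each sample centred on its median.

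Markers of other cell types that a muscle preparation could carry were mostly below the filter, except those of smooth muscle and pericytes. Of 23 measured fibroblast and fibro-adipogenic markers 16 lay below it, and of the 7 tested 5 fell and 1 rose on fibronectin, the same adjusted over the list alone (median log2 change -0.32, camera adjusted p = 0.0607), a list that passed with fry, with samples centred, with probe sets averaged, with the replicate number as a block and without fibronectin replicate 2. Smoc2, a matrix-associated protein, fell 2.18-fold, Islr fell 1.31-fold and Pdpn fell 1.29-fold. Smooth muscle and pericyte markers had 9 of 16 above the filter, 3 of them higher and 2 lower, again the same adjusted over the list alone (adjusted p = 0.85), with Rgs5 down 2.36-fold, Mcam up 1.93-fold from a collagen signal below the filter and Tagln, an actin-binding protein, up 1.83-fold. Endothelial markers had 3 of 18 above the filter, of which 0 changed. Macrophage and leukocyte markers had 3 of 22 above it, and 2 of these fell. Adipocyte markers had 4 of 10 above it, with 1 higher and 3 lower, and the Schwann cell and tenocyte markers 4 of 14, with 1 lower. The lower differentiation and lysosome genes on fibronectin were accompanied by lower signals of several fibroblast and adipocyte markers.

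Measures of RNA and labelling quality differed little between coatings for actin and the hybridisation spikes, and more for the labelling spikes and 18S ribosomal RNA. The signal of the 3' actin control probe set exceeded that of the 5' one by 0.69 ± 0.05 on collagen and 0.61 ± 0.04 on fibronectin, a change of -0.08. For 18S ribosomal RNA, which lacks a poly(A) tail, the same difference went from 0.25 ± 0.15 to -0.24 ± 0.31, a change of -0.49. Hybridisation spikes differed by 0.01 and labelling spikes by 0.20 on the log2 scale, the latter as large as the median changes of several called lists. Further probe sets of the labelling spikes, left out of that mean, differed by 0.007 to 0.474.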

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

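Both results here come from probe sets outside the comparison of named genes and were chosen after the data were seen. The control probe set for the mouse B1 repeat, a short interspersed element found in many transcripts, was higher in all 3 fibronectin samples (8.92, 9.00 and 9.08) than in any collagen sample (8.60, 8.43 and 8.37), a log2 difference of 0.54 between the means of the coatings. Of 2511 probe sets without an entry in the gene table that reached the brightness filter, 611 passed the limma threshold of an adjusted p of 0.05, 251 higher and 360 lower on fibronectin, or 24.3% against 32.9% of the bright probe sets with an entry.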

How the results depend on the processing

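Alternatives for the similarity of samples were chosen after the data were seen, and all others were fixed before. The count of 4384 changed genes was 572 with a minimum change of 1.5-fold (170 higher, 402 lower), 2569 at an adjusted p of 0.01 (1171 higher, 1398 lower) and 7196 over all probe sets (3652 higher, 3544 lower), each by construction of the rule. Other settings gave 3317 to 4824 genes, and leaving out 1 sample gave 3440 to 4139. Of 4174 of these genes also tested with all probe sets of a gene averaged 53 changed sign, 1 to 3 did so without 1 sample, and 0 did so with centring, quantile normalisation, no filter or array weights. The first component held 60.7% of the variance without the filter and 79% to 82.1% without 1 sample. The 10 lists kept their direction in every setting run, and 9 of them kept their call in each except that with an estimated correlation. With an estimated correlation 0 lists passed, at unchanged medians of -0.71, 0.28, 0.41, -0.12, 0.19, 0.26, -0.10, -0.24, 0.19 and -0.31 in the order differentiation, replication, mitosis, TGF-beta, glycolysis, Atf4, endoplasmic reticulum, Nrf2, ribosome biogenesis and lysosome. That setting changes both the correlation and the degrees of freedom of the test. For the Nrf2 list the estimated correlation of 0.013 was close to the preset 0.01, yet its unadjusted camera p went from 2.1e-07 to 0.00745. A higher correlation alone therefore does not account for the loss of that call. For the other lists the parts of the 2 changes were not tested. Without 1 sample the endoplasmic reticulum list, whose call depended on it, had medians from -0.115 to -0.079. The test fry, which differs from camera both in its null hypothesis and in how it treats correlation, called 26 lists. The collagen list passed with the 75th percentile filter and with averaged probe sets, and the immediate early list with that filter. Of 121 named genes past the threshold 7 lost the call in some setting and 0 changed direction. Genes that were not called and changed sign were, with averaged probe sets, Itga5 (-0.13), Itgb1 (-0.004), Myod1 (0.039) and Ccnd1 (0.089), with centring Itga7 (0.021), and without 1 sample Itga7 (-0.072 to 0.011), Itgb1 (-0.01 to 0.035) and Cdkn1a (-0.004 to 0.031), and the cause was not tested. With the replicate number as a block 4178 genes and 11 lists passed, the added list being the fibroblast markers. Deviations of samples with the same number correlated at 0.10, -0.01 and 0.08, so the numbers were not taken to pair the samples. Signals near the floor limit what can be read from the 7253 genes below the filter.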

Other observations

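The gene families in the first paragraph, the tests of array level, RNA quality, dilution, macrophages, adipocytes and lymphocytes, and the counts over other splits of the samples were chosen after the result was seen. The tests on related granzymes and further lysosomal targets were set before their values were seen, for patterns already seen. The tests first set for macrophages, adipocytes and lymphocytes compared levels of different probe sets, which cannot be compared, and were replaced after their values were seen. All 16 tested subunits of the vacuolar ATPase, the pump that acidifies lysosomes, fell on fibronectin (median log2 change -0.54, camera adjusted p = 2.7e-10 over 18 families, adjusted p = 0.161 with an estimated correlation), and the count was 16 with centring or quantile normalisation too. Of 9 cathepsins 7 fell and 0 rose (adjusted p = 4.06e-05, adjusted p = 0.257 with an estimated correlation), with the same counts under both scalings; Ctsd had a log2 change of -0.73. Cytosolic tRNA synthetases rose in 11 of 19 cases and fell in 0 (adjusted p = 0.00447, adjusted p = 0.384 with an estimated correlation). Nuclear pore proteins rose in 10 of 18 cases (adjusted p = 0.00138, adjusted p = 0.326 with an estimated correlation), with Nup37 at 0.48, and splicing factors of the SR and hnRNP families in 11 of 28 (adjusted p = 0.000525, adjusted p = 0.326 with an estimated correlation), a count that was 19 with centring and 10 with quantile normalisation. None of the members of these 3 families fell with centring or quantile normalisation. Mitochondrial ribosomal proteins (21 of 76 rose, 2 fell, camera adjusted p = 0.0113, 0.686 with an estimated correlation) and septins and kinesins (12 of 28 rose, 2 fell, 0.0112 and 0.257) passed too. The remaining families did not pass. Some vacuolar ATPase subunits, cathepsins and tRNA synthetases also belong to the lysosome or Atf4 lists, and some kinesins to the mitosis list. The families that hold them do not stand apart from those lists.

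Lower sarcomere and differentiation genes together with higher S phase and mitosis genes may reflect fewer cells leaving the cell cycle to differentiate on fibronectin, a hypothesis formed from these data that would need counts of dividing and fused cells. A uniform difference in array level was argued against only as far as the sample medians show it. Centring shifts all genes of a sample alike, so its outcome follows from those medians. It moved the share of higher genes from 49.6% to 64.4%, while the differentiation, replication and mitosis lists each kept at least 92.3% of their medians. An effect of scaling that varies with signal could not be seen this way. Quantile normalisation again, which makes the distribution of signals alike in all samples, gave these 3 lists medians of -0.684, 0.273 and 0.41. For these lists that argues against a difference in signal distribution between the samples. A scaling effect that leaves the distributions alike stays open. The muscle lineage genes Pax7, Myf5, Myod1, Cdh15, Itga7 and Ncam1 had a median change of -0.048 (SD over genes 0.15). Past the threshold 1 of them rose and 1 fell. These values argue only against a dilution by other cells large enough to give the differentiation list's median of -0.705. Pax7, Myf5, Myod1 and Itga7 had been seen not to pass before this test was set, so its outcome was largely known. A smaller dilution stays open. With 10 splits of the 6 samples a share under 0.05 cannot be reached. The real split gave 4384 genes and the highest other 0 (1 of 10 splits gave as many). For lists with the preset correlation the real split gave 10 and the other 9 splits gave 5 to 10 (3 of 10 gave as many). Each other split mixed the coatings unevenly, so part of their difference stayed between its groups and the rest widened the spread within them. The number of lists called thus did not set the real split apart, and neither count tells the coatings from chance. RNA quality stays open, since the 3' minus 5' signal moved by 0.078 in size for actin but by -0.49 for 18S ribosomal RNA, and so do cell density at harvest and other effects of the coating, which were not tested.

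Lysosome genes, the membrane protein Gpnmb (log2 change -1.63), the lipoprotein Apoe (-1.59), Fabp4 and Pparg were lower on fibronectin. Macrophages or adipocytes carried over on collagen cannot be told apart from a change within the myoblasts. The 6 abundant macrophage transcripts (median log2 change -0.012) and 5 of 6 abundant adipocyte transcripts (median -0.074 over all 6) lay below the filter, where an unmoved signal excludes nothing, while of the macrophage markers above it Cd68 and Cd14 fell (-1.28 and -0.46) and Csf1r did not pass (-0.03), and of the adipocyte markers Cebpa fell (-0.51) and Lpl rose (0.59). Lower activity of the transcription factors Mitf and Tfe3, which drive lysosomal genes and were themselves lower (log2 changes -0.69 and -0.24), is a candidate explanation that suggested a test on further targets, of which 29 of 32 fell and 1 rose (90.6% fell). Since these targets are lysosomal genes too, any cause that lowers lysosome genes together would give the same count, and factor activity was not measured.

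Gzmd and Gzme, granzymes known from cytotoxic lymphocytes, rose on fibronectin by 2.41 and 1.06 on the log2 scale, and a further probe set of Gzmd rose from 1.38 ± 0.11 to 3.59 ± 0.15. Zap70, Prf1 and Cd4, the 3 of 19 measured lymphocyte transcripts above the filter, did not rise with them. Their median change was -0.037 and 0 passed the limma threshold, although Ccl5, below the filter on collagen, rose by 0.72. The rest of the 19 lay below the filter, where an unmoved signal excludes nothing. A like signal of 3 transcripts on both coatings cannot exclude a few lymphocytes, so lymphocytes carried over on fibronectin stay open. Whether 1 granzyme gave the signal of both cannot be told apart, since the probe sets of related granzymes Gzmc, Gzmf, Gzmg and Gzmn lay near the floor (largest change 0.233), where an unmoved signal excludes nothing, and the probe set of Gzme is of a type that can bind related transcripts. Expression of a granzyme gene by the myoblasts themselves may account for the rise and was not tested.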
